A study of Carica papaya with 2 samples.

How the data were processed

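RNA from papaya (Carica papaya) leaf was measured by RNA sequencing in 2 samples, 1 control and 1 that had been given the freeze-thaw awakening treatment. Per the labels' protocols, plant material was held in a protective mixture of trehalose, glycol, glycerin and dimethyl sulfoxide at 26 °C for 72 hours. It was then cooled in steps of 0.5 °C each day over 180 days to a final -60 °C and left to thaw at room temperature. The same protocol text stands on both records, so the group of each library was taken from its treatment label, which marks the control as without the treatment. Whether the treated library came from the thawed leaf itself or from a plant grown afterwards is not stated in the labels. Total RNA was purified with a plant RNA column kit and made into libraries with a strand-keeping kit for polyadenylated RNA, per the labels' protocols.

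The submitters' processing notes name bcl2fastq 2.17, which turns sequencer output into reads, and RSEM 1.2.19, which estimates transcript and gene abundance. The assembler, genome build and annotation are not given in the sources used here. Each deposited file lists 1 value for each of the same 156240 contigs, whose names have the component, gene and contig parts that a de novo transcript assembler writes. Dropping the contig part left 101199 genes in 81733 components, a component being contigs that the assembler joined by shared sequence. In all 15329 genes with more than 1 contig, every contig carried the same value in both libraries. The deposited values were therefore read as gene values repeated on each contig, and each gene was used once.

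The unit is not named in the files or labels, and the deposited values were taken to be FPKM, fragments scaled by transcript length and by the library's total, made by the authors. They are mostly not whole, which excludes raw read counts but not estimated counts, which can be fractional. With each gene taken once they summed to 765874 in the control and 663069 in the treatment library. TPM over all genes would sum to 1000000 in each, although TPM over part of an assembly would not, so that reading stays possible. Whether the authors applied a further scaling between libraries is not stated. No read counts or contig lengths were used here, so the depth of each library is unknown and no counting intervals are given.

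The relative worth of a read was estimated from low values. Ratios of treatment to control were taken for genes at 1 to 8 FPKM in both libraries and counted in bins of 0.02 on the log2 scale. Whole reads give ratios that pile up at fixed steps. The fullest bin lay at 0.30, a ratio of 1.23, and held 195 genes against a mean of 123 in the bins around it. The bin 1 log2 unit lower held 157 genes against 54.8 around it. The bin at a log2 ratio of 0, where equal counts would fall, held 129 genes, and the bins beside it 115 and 154. Unscaled counts would pile up there, so this speaks against reading the values as estimated counts. If the values are FPKM with no further scaling, the control library was about 1.23 times as deep as the treatment library. The pile-up at the first ratio was 1.36 times the neighbouring bins for genes at 5 to 10 FPKM in the control and 1.01 times for genes at 10 to 20 FPKM. Values below 10 FPKM can thus rest on a handful of reads.

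Differences are treatment minus control on the scale of log2(FPKM + 1), which understates the difference of low genes, on values as deposited. Genes with a mean of at least 1 FPKM over the 2 libraries were compared, and those at least 2-fold apart on that scale were counted. With 1 library in each group there is no spread between replicates, so no test, p-value or standard error is given. Every difference describes these 2 libraries, not the conditions.

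The design fixed before the data were examined assumed counts with TMM scaling, a minimum on counts and 35 gene lists matched on product names. The values were not taken to be counts, so the fallback written there, log2(FPKM + 1) with no interval, was used. The FPKM minimum was set once the unit had been chosen. Contig names could not be paired with gene names or products, and the table of papaya RefSeq genes shares no identifier with them. No gene list was therefore used. By the rule for that case at most 2 genes higher and 2 lower are named, here those with the largest differences among genes with a mean of at least 5 FPKM.

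The calculation was tested on simulated data with the mean values of all 101199 genes, made-up lengths and depths, and 200 genes altered. Of the genes altered 4 times, 90% were found at least 2-fold apart, and of those altered 8 times, 93%. Of unaltered genes with a mean of at least 1 FPKM, 0.346% passed by counting error at the made-up depths. The real depths are unknown, so these shares do not carry over to the 2 libraries. A simulated read step of 0.322 was recovered as 0.32. Alternatives were other scalings, pseudocounts of 0.1 and 5, other minimum values, a 4-fold threshold, contigs in place of genes, and leaving out genes listed at 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.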

Results

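Leaf RNA of papaya was compared between 1 library from material given the freeze-thaw awakening treatment and 1 untreated control library. The title of the series asks how gene expression relates to growth after this treatment, and only expression was analysed here. The control library listed 76734 genes above 0 and 37711 genes at 1 FPKM or more. The treatment library listed 75277 genes above 0 and 34860 at 1 FPKM or more. A total of 64995 genes were above 0 in both libraries and 14183 were at 0 in both. The genes are known only by their assembly names, so no function can be attached to them. There was 1 library in each group, so none of the differences below could be set against a spread between replicates.

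The first comparison was of how each leaf library was made up. The most abundant transcripts took a larger part of the control library. Its 10 highest genes held 6.36% of the summed FPKM, against 4.44% for the 10 highest genes of the treatment library. The 100 highest genes held 17.39% in the control and 14.53% in the treatment library. Genes at 1000 FPKM or more numbered 37 in the control and 25 in the treatment library. The highest single gene reached 9521 FPKM in the control, and the highest in the treatment library, another gene, reached 4802 FPKM. The smallest set of genes that held 50% of the summed FPKM was 1838 genes in the control and 2043 in the treatment library.

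The most abundant genes differed between the libraries in identity as well as level. The lists of the 10 highest genes shared 4 genes, and the lists of the 100 highest shared 45. All 10 of the highest genes of the control were lower in the treatment library, 9 of them by at least 2-fold. Some of these genes, also among the shared ones, lie in the same component or share the first part of their assembly name. They need not be separate transcripts. Of the 10 highest genes of the treatment library, 6 were higher there than in the control, each by at least 2-fold, and the other 4 were the shared genes and were lower. Ranking in one library favours genes that are high in it, so the 100 genes with the highest mean over both libraries were also taken. Among these, 43 were at least 2-fold lower and 20 at least 2-fold higher in the treatment library, with a median log2 difference of -0.85.

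Some abundant genes lay far apart. One gene at 6281 FPKM in the control, the third highest of that library, was at 135 FPKM in the treatment library, 46.4 times lower. Another was at 3606 FPKM in the control and 20.5 FPKM in the treatment library, a ratio of 176, and one at 1497 FPKM stood at 26.7 FPKM, a ratio of 56.2. In the other direction, among genes at 1000 FPKM or more in the treatment library, the widest gap was 10.4 times, from 115.8 FPKM in the control to 1210 FPKM. The next were 5.72 times, from 185 to 1057 FPKM, and 5.31 times, from 694 to 3684 FPKM.

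As deposited, more genes were lower than higher in the treatment library. Of 38327 genes with a mean of at least 1 FPKM, 4701 were at least 2-fold higher in the treatment library (12.3%) and 9217 at least 2-fold lower (24.0%). The remaining 24409 genes lay within 2-fold. Of the lower genes, 5128 were at 0 in the treatment library, and of the higher genes, 1333 were at 0 in the control. On this scale a gene at 0 in 1 library always passes 2-fold once its mean is at least 1 FPKM. The median log2 difference was -0.03 and the middle 50% of genes lay between -0.93 and 0.51. At 4-fold the counts were 1421 higher and 5146 lower. Across these genes, which are not independent replicates, Pearson's r of the log2 values was 0.691 and Spearman's rho 0.588. Among the 31866 that were above 0 in both libraries, r was 0.836 and rho 0.785. Of the genes above 0 in both libraries, a choice that leaves out genes by their difference, 3368 were higher and 4089 lower as deposited, and 4043 were higher and 3645 lower with sums made equal over these genes.

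**Figure D1:**
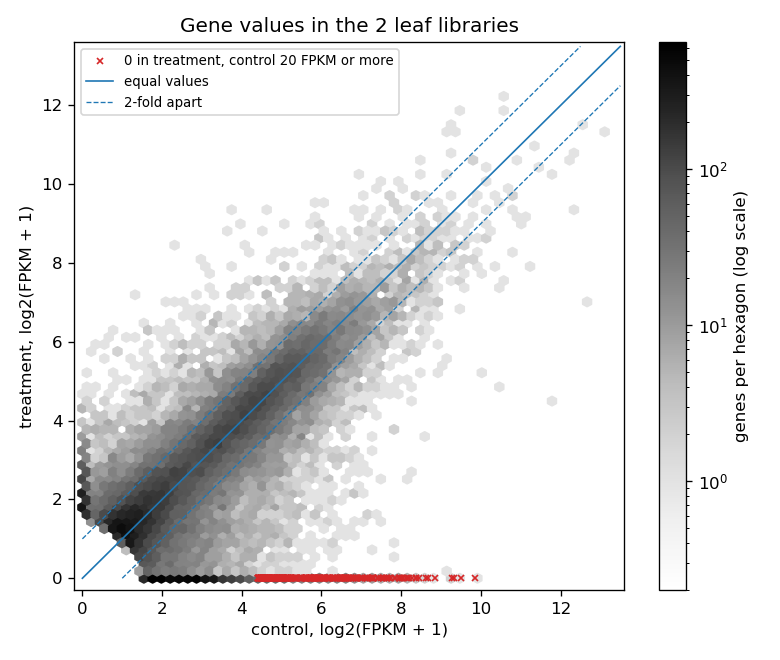
Value of each gene with a mean of at least 1 FPKM in the control (x axis) and treatment (y axis) library, both as log2(FPKM + 1), with darker hexagons for more genes on a log scale. The solid line marks equal values, the dashed lines 2-fold differences, and the red crosses the 339 genes at 20 FPKM or more in the control that are listed at 0 in the treatment library.

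Lower and higher genes were both found at all levels of abundance. Of the lower genes, 2665 had means of 1 to 2 FPKM and 3438 means of 2 to 5 FPKM. The higher genes numbered 1541 and 1235 at these levels, where values can rest on few reads. Between means of 2 and 5 FPKM, 34.5% of 9976 genes were at least 2-fold lower and 12.4% at least 2-fold higher. Between 20 and 50 FPKM, 14.1% of 5014 genes were lower and 9.59% higher. The shares were closest between 50 and 100 FPKM, with 15.7% of 1723 genes lower and 13.0% higher. At a mean of 100 FPKM or more, 242 of 996 genes were lower and 165 higher, with a median log2 difference of -0.25. The shares also differed by how a gene was assembled, a comparison of these 2 libraries with no test. Of 25507 single-contig genes, 28.2% were lower and 13.7% higher, against 15.7% and 9.33% of 12820 genes with 2 or more contigs. These groups were not matched on level, and the shares above differ by level, so this contrast can reflect level.

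A separate group of genes was present in the control and listed at 0 in the treatment library. At 20 FPKM or more in the control, 339 of 7752 genes (4.37%) were at 0 in the treatment library. The opposite, 20 FPKM or more in the treatment library and 0 in the control, held for 4 of 7346 genes (0.054%). At 100 FPKM or more the numbers were 69 of 1090 genes in the control (6.33%) and 0 of 946 genes in the treatment library. The highest gene of this group stood at 918 FPKM in the control, whereas the highest value of any gene at 0 in the control was 27.3 FPKM. At 5 FPKM or more, a level at which values can rest on few reads, 2500 genes were at 0 in the treatment library and 220 in the control. The genes at 0 in the treatment library made up 7.59% of the summed FPKM of the control. Those at 0 in the control made up 1.65% of that of the treatment library. Which reads were assembled is not known here. A transcript without a contig is listed in neither library, so the unequal counts can be partly built in.

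**Figure D2:**
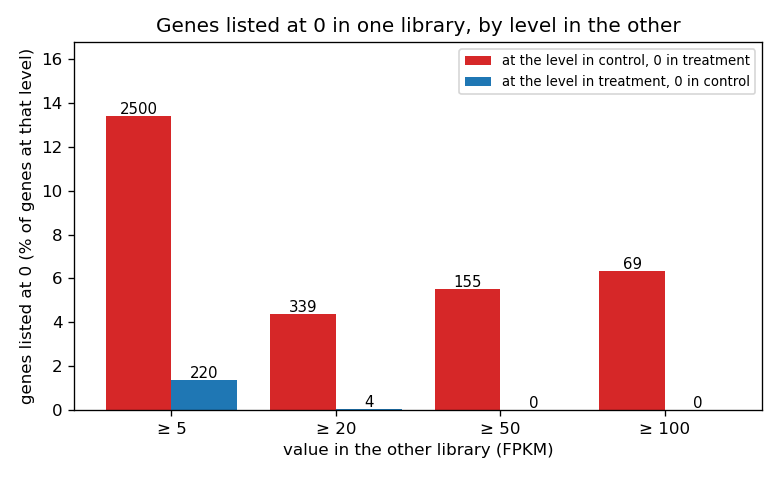
Percentage of genes listed at 0 in one library (y axis) among genes at or above 5, 20, 50 or 100 FPKM in the other (x axis), with the number of genes above each bar. Red bars are genes present in the control and at 0 in the treatment library, from 2500 genes at 5 FPKM to 69 at 100 FPKM, and blue bars are the reverse, from 220 genes to 0.

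Genes at 0 outnumbered those at very low values in the treatment library. Of 2817 genes at 50 FPKM or more in the control, 155 were at 0 in the treatment library and 25 were above 0 but below 1/64 of the control value. A further 99 lay between 1/64 and 1/8 of it, 600 between 1/8 and 0.5, and 1938 at 0.5 of it or above. The class just above 0 is narrowed by detection, since for some genes 1/64 of the control value can be less than 1 read. Among genes at 5 FPKM or more in the control, 13.4% of those at 0 in the treatment library had 2 or more contigs, against 53.1% of the others. These groups were not matched on level. Of the 2500 genes at 0, with a median of 7.72 FPKM in the control, 339 reached 20 FPKM there, against 7413 of the 16146 others. The contrast in contigs can therefore reflect level.

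Of the 17190 genes with a mean of at least 5 FPKM, 14 were at least 32-fold higher in the treatment library and 263 at least 32-fold lower. Of these 263, 35 were above 0 in the treatment library. The largest difference upwards among them was that of TR45642|c0_g1, at 3.92 FPKM in the control and 356.87 FPKM in the treatment library, a log2 difference of 6.18. TR33081|c0_g1 followed, at 1.65 and 149.74 FPKM, with a log2 difference of 5.83. The control values of both genes lie below 10 FPKM and can rest on a handful of reads, so the sizes of these differences are uncertain. The largest differences in the other direction belonged to TR43062|c3_g3, at 917.99 FPKM in the control, and TR4947|c61_g4, at 726.54 FPKM. Both were listed at 0 in the treatment library, so no fold is given for them.

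**Figure D3:**
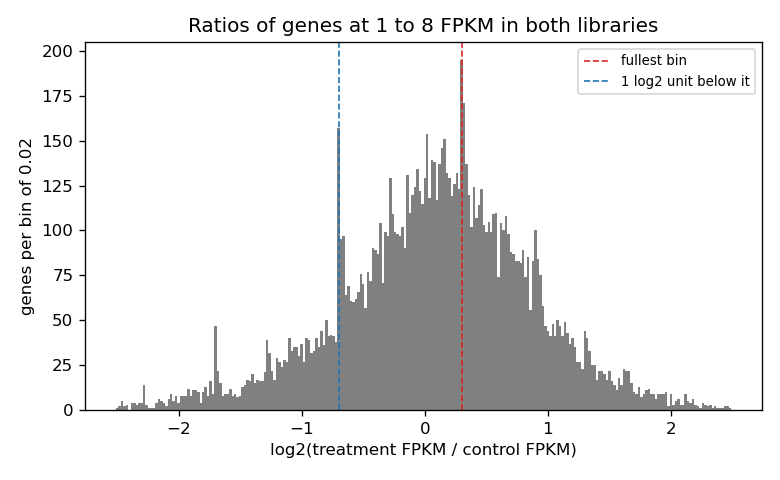
Number of genes (y axis, per bin of 0.02) by the log2 ratio of treatment to control FPKM (x axis), for genes at 1 to 8 FPKM in both libraries. The red dashed line marks the fullest bin, at 0.30 with 195 genes, and the blue dashed line the pile-up 1 log2 unit below it, with 157 genes.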

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

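All alternatives here except the 4-fold threshold and the absence of a minimum value were chosen after seeing the data. As deposited, 4701 genes were at least 2-fold higher and 9217 lower, so that 66.2% of the genes apart were lower. The count of higher genes was 1622 with a pseudocount of 5, 1925 at a mean of at least 5 FPKM, 1320 at 10 FPKM, 1421 at 4-fold and 9588 when every contig was counted as listed. The count of lower genes under the same settings was 4480, 3114, 2018, 5146 and 16248. Higher minimum values leave fewer genes to compare, and contigs repeat the value of their gene. At 4-fold the share lower was 78.4%. Without genes at 0 in either library 4089 genes were lower, a share of 54.8%. That choice leaves out genes by their difference, so the fall in lower genes is partly built in, and equal sums then raise all treatment values by 1 factor. Both together gave 3387 lower genes (42.1%) with sums equal over all genes, with a median log2 difference of 0.249, and 3645 (47.4%) with sums equal over the genes above 0 in both, with a median of 0.172. Without the components holding a gene at 20 FPKM or more in the control and 0 in the treatment library, 8741 genes were lower (65.0%). That choice also picks by the difference, and the count of higher genes stayed at 4701. Equal sums over all genes alone multiplied the treatment values by 1.16, moved the median log2 difference from -0.035 to 0.155 and left 57.3% lower; the other scalings left 58.5% to 69.2% lower. With pseudocounts of 0.1 and 5 the log2 difference of TR45642|c0_g1 was 6.47 and 5.34, and that of TR33081|c0_g1 6.42 and 4.54. TMM and median-of-ratios factors on counts, thinning to equal depth, the most abundant transcript alone and all alternatives for gene lists were not run, since they need counts, transcript values or gene names. No replicate could be left out, and what depth limits could not be given as an interval.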

Other observations

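The tests of the genes at 0 in the treatment library were chosen after the values behind them had been seen. So were those of the balance of lower and higher genes by genes at 0 alone and by low values. The tests by scaling, alone and together with genes at 0, were set after the data had been seen but before their own results.

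Genes of the same component tended to be at 0 in the treatment library together. The 339 genes at 20 FPKM or more in the control and 0 in the treatment library lay in 219 components. In 101 of these no other gene was above 0 in either library. Of the 118 components with 2 or more genes above 0 in either library, 117 had every gene at 0 in the treatment library, but some of these hold only genes picked for being at 0. Leaving the 339 genes themselves out, 139 of them had a neighbour, and 154 of 155 neighbours (99.35%) were at 0. For the 7413 genes at that control level that were above 0 in the treatment library, counted in the same way, it was 73 of 2502 neighbours (2.92%). A second count took genes and neighbours at 5 FPKM or more in the control, with the picked genes counted as neighbours of each other. There 90.8% of the neighbours of genes at 0 were at 0, against 0.74% for genes above 0. The same search in the treatment library gave 8 of 58 neighbours of genes at 0 in the control (13.8%), against 0.51% for genes above 0, so neighbours shared zeros in that direction too, in a smaller part.

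The ratio of about 1.23 is one of depth only if the values are FPKM with no further scaling. Under that condition, depth would not account for members of this group whose control value rests on many reads. How many reads lie behind a value is not known without read counts or contig lengths, so depth is not excluded here. Of the genes at 100 FPKM or more in the control, 6.33% were at 0 in the treatment library. No gene at that level in the treatment library was at 0 in the control, a count that covers assembled contigs only. A strain variant between the plants that differed only in sequence would leave reads on the other variant, and only that kind is weighed here. The 155 neighbours, taken at any level above 0 in either library, had a median log2 difference of -3.03 and none was higher. As 154 of them were at 0 in the treatment library, these values restate the 99.35% above. Genes at 50 FPKM or more in the treatment library and 0 in the control numbered 0, against 155 the other way. That count covers assembled contigs only, and which reads were assembled is not known here, so it cannot decide on a variant. For genes with no such neighbour nothing here speaks against a variant. A variant assembled in another component and present in both libraries stays open as well. RNA of another organism in the control leaf is a candidate explanation. The 99.35% of neighbours also at 0 cannot tell it from other explanations. Genes of 1 component share sequence and can be parts of 1 transcript, which could be at 0 together for other causes too. Another organism is a hypothesis found and tested on the same libraries. A set of papaya genes silent in the treated leaf, and reads given to near-identical contigs elsewhere, stay open, because contig sequences were not used here.

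More genes were lower than higher in the treatment library, 1.96 lower for each higher. Scaling had no single outcome. Equal sums left 1.34 lower per higher gene, between the limits of 1.1 set for a cause and 1.5 set against it. Median ratio scaling gave 2.10 and trimmed mean scaling 2.25. These last scalings lowered the treatment values, by factors of 0.976 and 0.952. The median log2 difference over the compared genes moved with them from -0.035 to -0.067 and -0.1. Every scaling here multiplies the treatment values by 1 factor, whose side of 1 sets which way the ratio moves. The scalings thus show only that the balance depends on the factor, and scaling is left open as a cause. Keeping only means of at least 10 FPKM left 1.53 and of at least 5 FPKM 1.62. Both are over 1.5, the first only just, and with 1 library in each group there is no spread between replicates to set that against, so low values are left open as a cause. Leaving out genes at 0 gave 1.21 alone and 0.727 with equal sums, but it picks genes by their difference, so neither value shows a cause. Without the components that held a gene at 20 FPKM or more in the control and 0 in the treatment library the ratio was 1.86. That choice also picks by the difference, so the direction of this fall is built in. Genes at 0 at any level were many more: 5128 of the 9217 lower genes were at 0 in the treatment library and 1333 of the 4701 higher genes at 0 in the control. Each of these genes passes 2-fold by the minimum mean and the scale alone. What lies behind the excess cannot be told apart here, and an effect of the treatment stays open and untested.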
